A study of Mus musculus with 15 samples.

How the data were processed

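Expression was measured by RNA sequencing in 15 libraries of 5 mouse myeloma cell lines with 3 technical replicates each, per the labels. RNA had been extracted with the RNeasy mini kit and made into libraries with the TruSeq Stranded Total RNA kit, per the labels' protocols. Trim Galore 0.4.0, DESeq2 without a version and the GRCm39 build are named in the submitters' processing notes. The aligner, the quantifier and the annotation are not given in the sources used here.

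The deposited table held 32434 entries under 32371 gene names, with 1 value per entry and library, and was named for TPM, a unit scaled for transcript length. Its values were taken as estimated counts, since the deposited columns sum to 19068543 to 41165599 per library and not to the same total, and since 30.8% to 54.3% of the values above 0 and under 1.5 in each library lie within 0.02 of 1, as estimated counts of a single read do. A further deposited column equalled the mean of the 15 libraries to within 6e-05 and was not used. Before the data were examined, limma on log2(TPM + 1) had been set as the test. Because the deposited values are estimated counts, they were rounded to whole numbers and tested with edgeR's quasi-likelihood test instead, and limma on log2(CPM + 1) became an alternative. Estimated counts that were corrected for transcript length by a quantifier would carry that correction into the levels given here.

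Gene names in the table are in capitals and were matched without regard to case to mouse symbols of a gene table of the GRCm38.p6 assembly. A match was found for 32186 entries (99.2%), and 118 entries shared a name with another and were kept apart. Since that assembly is not the build of the submitters, no coordinates are given, and chromosomes were taken from it by name. Ighg1, Ighg2a, Trac, Trbc1, Hbb-bs, mt-Rnr1 and mt-Rnr2 were not analysed here.

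Genes with at least 1 CPM in at least 3 libraries were tested (11773 genes). Library sizes were scaled by TMM, with factors from 0.848 to 1.08, and levels are CPM on those sizes. Models were fitted in edgeR 4.0.16 with R 4.3.3 to all 15 libraries with the cell line as the single factor, so that the lines shared a dispersion estimate. 3 kinds of comparison were made: an F-test over the lines, each line against the mean of the other 4, and each pair of lines. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1 (for the F-test, between the highest and the lowest line). For 194 tested genes all 3 libraries of at least 1 line had 0 counts. Their fitted log2 difference depends on the prior count, so levels are given for them, with folds against a floor of 3 counts over the line as lower bounds. The stricter count "singly" asks for a call in the same direction against each of the other 4 lines.

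Gene lists were fixed before the data were examined: 26 lists with 509 members in all. They covered plasma cell identity, mature B cells, both MHC classes, immunoglobulin constant genes, oncogenes and tumour suppressors of myeloma, IL6 JAK STAT3, NF-kB and RAS MAPK signalling, MYC and p53 targets, proliferation, the unfolded protein response, glycolysis, the BCL2 family, bone disease, adhesion, therapy targets, interferon response, mitochondrial transcripts, sex-linked transcripts and markers of 4 other kinds of cell. Lists with at least 5 tested members (24 of them) were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01, with adjustment over all lists and the 5 contrasts together. A second run estimated the correlation, and its adjusted p is printed where the call was lost. Named genes follow a rule fixed before the data were examined. For each line it takes the 10 highest and 10 lowest log2 differences among called genes with all 3 libraries outside the range of the 12 other libraries and at least 5 CPM on the higher side (set as TPM beforehand). It leaves out V, D and J segments, pseudogenes and predicted genes. It adds up to 4 called members per list and line, a fixed set of myeloma genes, and other-cell markers at 5 CPM or more. The text gives a selection of these genes.

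Shares of V segments and constant genes were computed per library from the counts of each locus. Distances and principal components were computed on log2(CPM + 1). For chromosomes, the median log2 difference of the genes of a chromosome was compared with 10000 random gene sets of the same size, and a shift was called at an adjusted p under 0.05 and a size of at least 0.2.

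The 3 libraries of a line were compared before they were averaged. None of the pairs within a line held the same values, and their counts differed by more than sampling noise, with a chi-square per degree of freedom of 4.33 to 18.4. They were kept as 3 replicates. The tests were run on simulated counts for IL6Myc-1 against the other 4 lines over 11773 genes. Of 100 genes changed 2-fold, 96 were significant with the right sign and 43 passed the size threshold as well, and of 100 genes changed 4-fold, 100 were called. Among 11061 unchanged genes 5 were called, and 0 were called singly. In the same simulation 4 chromosomes had an adjusted p under 0.05 though 1 had been shifted, and the minimum shift of 0.2 was set for that reason.

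The alternatives were other filters, scalings, pseudocounts, variance models and size thresholds, a replicate block, leaving out each library and each line in turn, leaving out immunoglobulin and mitochondrial genes, and DESeq2 1.42.0.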

Results

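RNA was sequenced from 5 mouse myeloma cell lines, IL6Myc-1 to IL6Myc-5, established from IL6Myc mice, an immunocompetent model of multiple myeloma, the cancer of antibody-secreting plasma cells. Each line was represented by 3 technical replicate libraries, 15 in all, and no normal plasma cell or untransformed control was part of the panel. The comparisons that this design allows are those of the lines with each other: how far their transcriptomes lie apart, and which genes and gene groups set each line apart from the other 4. The libraries held 19068543 to 41165599 estimated counts each. The largest library belonged to IL6Myc-1, whose 3 libraries held 41165599, 25205985 and 20004713 estimated counts. Levels are given as CPM, counts scaled to a common library size, as mean ± SD over the 3 libraries of a line. A count of 0 over those 3 libraries is given with the level that 3 counts allow, and such limits cover counting error only. The p-values measured the spread between technical replicates of a line, and each line was a single biological unit.

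All 5 lines carried high levels of plasma cell transcripts. Igha, the constant region of the IgA heavy chain, ranged from 18000 ± 930 CPM in IL6Myc-4 to 41600 ± 820 CPM in IL6Myc-2, and Igkc, the kappa light chain constant region, from 15200 ± 1100 CPM in IL6Myc-1 to 53700 ± 520 CPM in IL6Myc-2. Xbp1, a driver of the secretory programme, lay between 1570 ± 34 and 1900 ± 28 CPM. Irf4 and Prdm1, transcription factors of plasma cell identity, lay between 964 ± 16 and 1200 ± 36 CPM and between 167 ± 5.5 and 196 ± 11 CPM. Sdc1, which encodes the plasma cell surface marker CD138, ran from 284 ± 9.1 CPM in IL6Myc-2 to 582 ± 15 CPM in IL6Myc-4. Myc was measured at 1030 ± 43 CPM in IL6Myc-3 to 1530 ± 60 CPM in IL6Myc-2. Of these 7 genes, Igkc in IL6Myc-2 was the one that passed both thresholds for a difference of a line from the other 4 (log2 difference 1.53 ± 0.04 SE, edgeR adjusted p = 1.06e-15).

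Among the D-type cyclins, which drive entry into S phase, Ccnd2 was the most abundant in each line, from 861 ± 14 CPM in IL6Myc-2 to 1870 ± 11 CPM in IL6Myc-1. Ccnd3 lay between 20.6 ± 1.3 and 40.3 ± 2.9 CPM, and Ccnd1 had at most 1 count over the 3 libraries of a line. Il6 had 0 counts in all 15 libraries, which allows a level of up to 0.0332 CPM in IL6Myc-1 and up to 0.0527 CPM in IL6Myc-2, whereas the IL-6 receptor genes Il6ra and Il6st were measured in each line, at 13.5 ± 0.46 to 48.2 ± 4.2 CPM and 108 ± 10 to 282 ± 7.2 CPM. A count per mouse gene does not separate the transcripts of a transgene from those of the endogenous gene, and a human transgene would not be counted under a mouse name. Trp53, the p53 tumour suppressor, ran from 80.8 ± 2.1 CPM in IL6Myc-4 to 148 ± 2.9 CPM in IL6Myc-2, and Cdkn2a from 29.5 ± 1.4 to 41.5 ± 2.2 CPM. Neither Trp53 nor Cdkn2a passed the size threshold in any line.

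**Figure D1:**
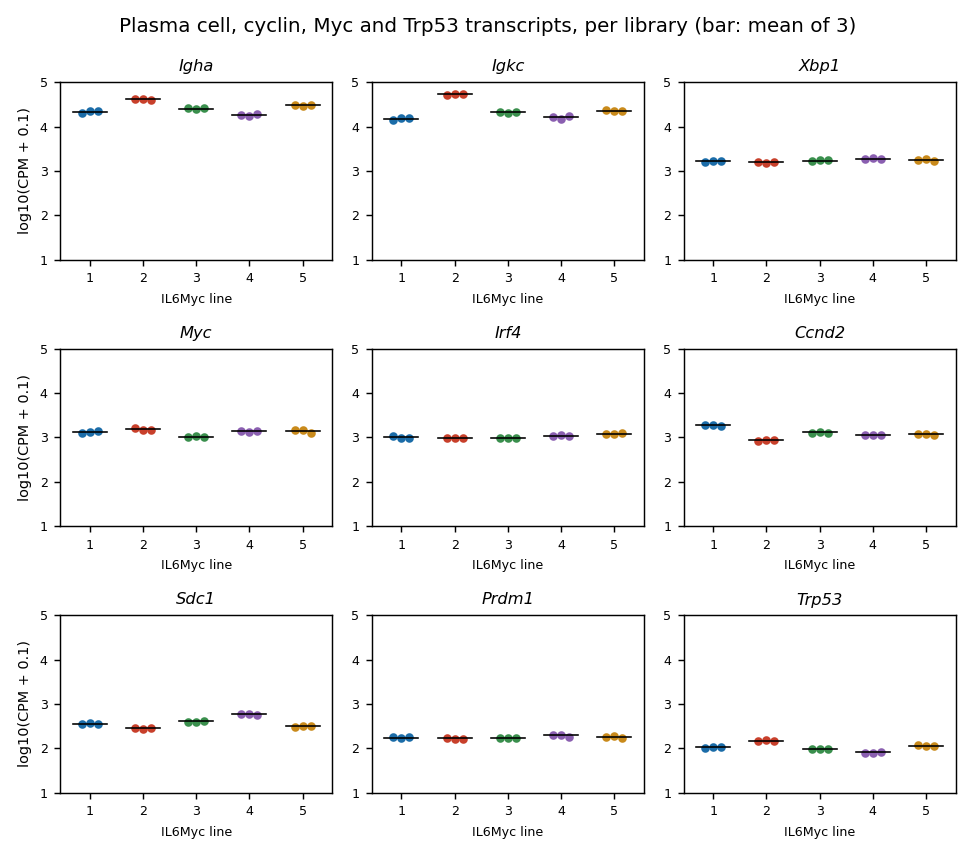
Level of 9 genes in each library, as log10(CPM + 0.1) on the vertical axis, with the 5 lines on the horizontal axis, a point per library and a black bar at the mean of 3. The means of Igha and Igkc stand at 15200 CPM or more in every line, and those of Myc between 1030 and 1530 CPM.

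The lines lay well apart from each other when set against the technical spread. Over the 11773 genes tested, Pearson's r across genes was 0.994 to 0.997 between libraries of the same line and 0.918 to 0.967 between libraries of different lines. The mean Euclidean distance on the log2(CPM + 1) scale was 22.6 within lines and 76.4 between lines. The closest lines were IL6Myc-3 and IL6Myc-5, with a mean distance of 61.6, and the farthest were IL6Myc-1 and IL6Myc-2, with 97.7. The first 4 principal components held 38.8%, 24.8%, 15.9% and 13.5% of the variance, and the fifth held 1.1%.

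**Figure D2:**
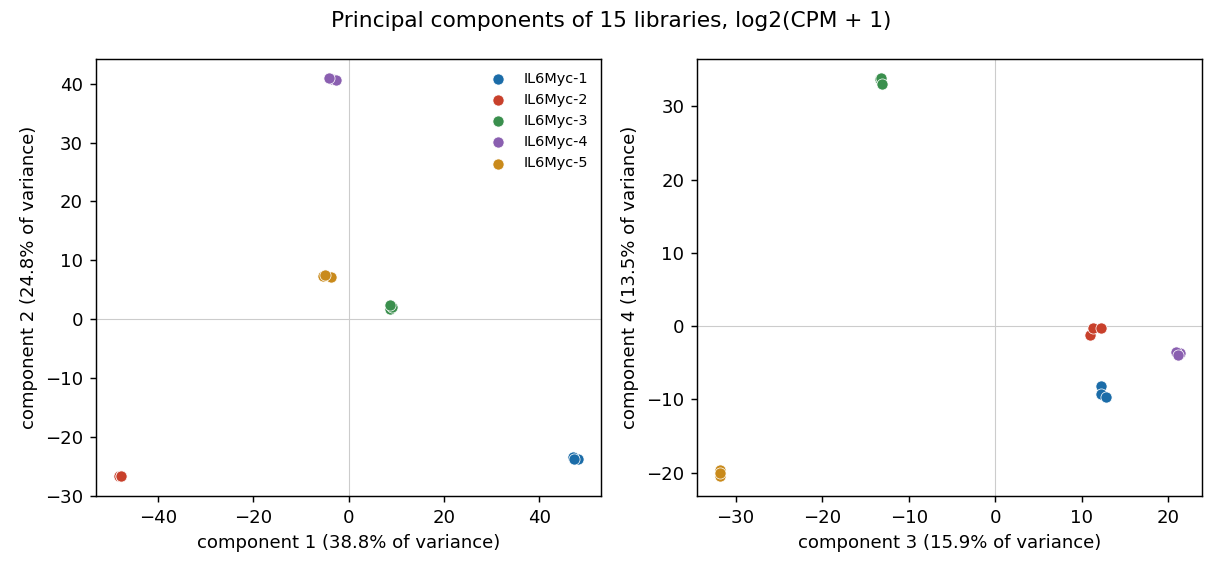
Scores of the 15 libraries on principal components 1 and 2 (left) and 3 and 4 (right), each axis with its percentage of the variance, computed on log2(CPM + 1) and coloured by line. The 3 libraries of a line fall together, IL6Myc-1 and IL6Myc-2 lie at opposite ends of component 1, and IL6Myc-4 lies at the upper end of component 2.

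In all, 3783 genes (32.1% of those tested) differed among the 5 lines, with an adjusted p under 0.05 in edgeR's quasi-likelihood F-test and at least 1 log2 unit between the highest and the lowest line. At any size, 10797 genes passed the F-test, and the median biological coefficient of variation between technical replicates was 0.064. Between pairs of lines, 2238 genes differed between IL6Myc-1 and IL6Myc-2 (1448 of them higher in IL6Myc-2), 1844 between IL6Myc-1 and IL6Myc-4, 1714 between IL6Myc-1 and IL6Myc-5 and 1337 between IL6Myc-1 and IL6Myc-3. IL6Myc-2 differed from IL6Myc-3, IL6Myc-4 and IL6Myc-5 in 1648, 1645 and 1438 genes. The counts were 1359 for IL6Myc-3 and IL6Myc-4, 1332 for IL6Myc-4 and IL6Myc-5, and 1161 for IL6Myc-3 and IL6Myc-5. A gene was called for a line when it differed from the mean of the other 4 lines, and more strictly when it also differed in the same direction from each of those 4 lines singly. At least 1 line was set apart singly by 1418 genes. Raising the filter to 5 CPM in 3 libraries left 2449 genes differing among the lines, and testing on log2(CPM + 5) left 1595.

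IL6Myc-2 stood out by its NF-kB and antigen presentation genes. Map3k14, which encodes the NF-kB inducing kinase NIK, was at 142 ± 8.7 CPM in IL6Myc-2 and at 2.58 to 3.004 CPM in the 4 other lines, 47.2-fold above the nearest of them (log2 difference from the mean of the 4 lines 5.66 ± 0.05, edgeR adjusted p = 9.84e-21). Ltb, the lymphotoxin beta gene, reached 276 ± 4.4 CPM against 0.0397 to 0.190 CPM elsewhere. Nfkbia, the gene of the inhibitor IkB alpha, was 3.93-fold above the nearest line at 251 ± 5.53 CPM, and Tnf was 8.27-fold above it at 11.4 ± 0.955 CPM. Of the 20 tested members of the NF-kB pathway list, 11 were called higher in IL6Myc-2, 0 lower, and 9 were not called (camera adjusted p = 1.67e-32). Nfkb2 and Relb, subunits of the alternative NF-kB pathway named here after their values were seen, were at 188 and 22.5 CPM, against at most 37.4 and 9.65 CPM in the other lines.

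MHC class II transcripts were called higher in the same line for 4 of 5 tested members (camera adjusted p = 4.11e-25). Cd74, the invariant chain that escorts class II molecules, was at 2698 ± 60.1 CPM in IL6Myc-2 and at 66.1 to 175 CPM in the others. H2-Ab1 was at 16.5 ± 1.43 CPM and had 0 counts in the 12 libraries of the other lines, at least 387-fold higher against the largest of their floors of 3 counts per line, although without the reads such a 0 cannot be read as absence of the transcript. H2-Eb1 was 14.3-fold above the nearest line at 13.5 ± 0.707 CPM. Of the 15 class I presentation genes, 7 were called higher and 0 lower (camera adjusted p = 2.26e-15), among them Tapbp, the gene of the peptide loading factor tapasin, at 361 ± 3.9 CPM and H2-K1 at 857 ± 4.44 CPM. H2-Q6 and H2-Q7 were also called, although H2-Q7 was at 85.2 ± 9.07 CPM in IL6Myc-5 and 82.1 ± 2.42 CPM in IL6Myc-2, and reads of these near-identical class I genes can be split among them. Immunoglobulin constant genes were called higher for 6 of 9 (camera adjusted p = 3.05e-42), with Iglc2 at 1164 ± 26.6 CPM, 4.43-fold above the nearest line, and Ighg3 at 48.4 ± 2.14 CPM, 43.1-fold above it. Immunoglobulin transcripts took 12.4 ± 0.134% of the counts of IL6Myc-2, against 5.71 ± 0.198% to 7.27 ± 0.151% in the other lines. Its libraries also stood apart in the 18S ribosomal transcript Rn18s, with 0.539 ± 0.0125% of the counts against 0.223 ± 0.0803% to 0.362 ± 0.0297%. Some myeloid markers stood higher in this line too, with Itgam at 11.6 ± 0.226 CPM against at most 3.65 CPM and Fcgr4 at 27.6 ± 0.764 CPM against at most 10.9 CPM. Cd68 was also called, at 202 ± 6.18 CPM against 186 CPM in IL6Myc-4, while C1qb was lowest in this line, at 66.9 CPM. The myeloid list was not called (3 of 8 higher, 1 lower, camera adjusted p = 0.0645). Nor was the T and NK cell list (3 of 6 higher, 2 lower, camera adjusted p = 0.553).

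Also higher in IL6Myc-2 were Pim1 and Pim2, serine/threonine kinases that promote survival, at 1135 ± 37.6 and 137 ± 0.846 CPM, 2.62-fold and 7.49-fold above the nearest line. Itgb3 (integrin beta 3) was at 80.3 ± 3.58 CPM against at most 11.6 CPM, and Ikzf3, a target of immunomodulatory drugs in myeloma, at 48.1 ± 5.74 CPM against at most 13.0 CPM. Cd52 was at 399 ± 11 CPM, 2.63-fold above the nearest line, and Sel1l, a component of endoplasmic reticulum degradation, at 2168 ± 17.2 CPM against 936 to 1006 CPM. The unfolded protein response list was higher, with 2 of 26 members called (camera adjusted p = 0.000274). The IL6 JAK STAT3 list had 5 of 16 members called higher (camera adjusted p = 0.0134, but adjusted p = 0.127 with an estimated correlation), the myeloma oncogene list 3 of 19 (adjusted p = 0.0134, and adjusted p = 0.0507 with an estimated correlation), and the glycolysis list 2 of 20 (adjusted p = 0.0224, and adjusted p = 0.295 with an estimated correlation). The proliferation list was lower as a group in camera with 0 of 30 members called (median log2 difference -0.43, adjusted p = 8.84e-07).

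Lower in IL6Myc-2 were Tfrc, the transferrin receptor gene, at 230 ± 4.24 CPM against 634 to 961 CPM, and Ly6k, with 1 count against 149.9 to 217 CPM. Ifi204 and Ifi207, interferon-inducible genes with close relatives in the genome, were with 3 counts and 2 counts against at least 7.35 and 2.36 CPM. Slc25a4, a mitochondrial ADP/ATP carrier gene, was listed with 1 count in IL6Myc-2 against 27.8 to 48.7 CPM elsewhere, and Egln1, an oxygen sensor gene, was at 25.4 ± 0.717 CPM in IL6Myc-2 and listed at 0 in the 12 libraries of the other lines. Both are widely expressed genes, and without the reads a level near 0 in a whole line cannot be read as absence of the transcript. In IL6Myc-2, 1013 genes were higher and 480 lower than the mean of the other lines, and 364 and 130 of them also differed from each line singly. With limma on log2(CPM + 1), 248 genes were lower.

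Of the transcription factor genes of the Hedgehog pathway, which was not among the gene lists, Gli1 and Gli3 were called higher in IL6Myc-4. Gli1 was at 958 ± 55.3 CPM, 793-fold above the nearest line at 1.21 CPM (log2 difference 10.96 ± 0.07, edgeR adjusted p = 8.1e-23), and Gli3 at 17.1 ± 0.488 CPM, 64.5-fold above it. Cxcr3, a chemokine receptor of lymphocytes, was at 134 ± 0.975 CPM and 186-fold above the nearest line. Tyk2, a Janus kinase that signals for cytokine receptors, was at 295 ± 6.85 CPM, 3.49-fold above the nearest line, and Il6ra, the IL-6 receptor alpha chain, at 48.2 ± 4.23 CPM, 2.24-fold above it. With Il6st and Socs2, these made 4 of 16 members of the IL6 JAK STAT3 list called higher, with 0 lower. The camera test of this list had an adjusted p of 0.039, lost with an adjusted p = 0.19 with an estimated correlation, and its median log2 difference of -0.16 was opposite in sign to its mean of 0.22.

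Adhesion and homing genes were higher as a group in IL6Myc-4 (2 of 19 called higher, 1 lower, camera adjusted p = 2.36e-09), with Itga5 at 56.2 ± 4.3 CPM beside Cxcr3, and with Ccr2 lower at 0.163 ± 0.0256 CPM. Hk2, the glycolytic enzyme hexokinase 2, was at 243 ± 20.7 CPM, 4.34-fold above the nearest line, and Aldoc at 122 ± 6.03 CPM, although the glycolysis list as a whole was not called (camera adjusted p = 0.69). The mature B cell list was higher (2 of 7 called, camera adjusted p = 0.0011), with the antigen receptor gene Cd79b at 564 ± 20.5 CPM and Ebf1 at 30.8 ± 1.6 CPM. Therapy targets and checkpoints were higher (2 of 18 called, camera adjusted p = 0.00209), with Tnfrsf17, which encodes BCMA, at 37.1 ± 1.4 CPM and Ikzf3 at 13.0 ± 0.96 CPM. Tnfrsf17 was higher in IL6Myc-1, at 47.6 ± 3.5 CPM, and Ikzf3 in IL6Myc-2, at 48.1 ± 5.74 CPM. Of this list and of the mature B cell list, 0 members were higher in IL6Myc-4 than in each line singly. Genes listed as markers of other cell types moved in this line too: of the myeloid list C1qb was at 490 ± 25.9 CPM against 66.9 to 113 CPM and C1qc at 65.8 ± 1.38 CPM against at most 20.4 CPM (2 of 8 called higher, camera adjusted p = 7.02e-11), while Lyz2, Cd14 and Csf1r stayed at 0.0257 CPM or less there. Of the T and NK cell list 5 of 6 were called higher (camera adjusted p = 2.34e-06), among them Prf1, the perforin gene, at 14.8 ± 1.41 CPM and Cd3g at 22.0 ± 0.469 CPM, while Cd3e was at 0.0119 CPM and Gzmb had 0 counts. Of these 5, 1 was higher than each line singly. Cd3g was at 12.5 CPM in IL6Myc-1 and 10.8 CPM in IL6Myc-2.

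Lower in IL6Myc-4 were the class I genes H2-Q7, at 3.37 ± 0.401 CPM against 50.4 to 85.2 CPM, and H2-Q6, at 18.9 ± 0.989 CPM against at least 67.98 CPM, with 4 of 15 presentation genes called lower (camera adjusted p = 4.47e-07, lost with an adjusted p = 0.0564 with an estimated correlation). Rnf130, a ubiquitin ligase gene, and Rassf3 had 0 counts in IL6Myc-4 and were at least 153-fold and 104-fold lower than in the nearest line, although without the reads such a 0 cannot be read as absence of the transcript. Igfbp3, which encodes an insulin-like growth factor binding protein, had 1 count against 9.98 to 33.2 CPM elsewhere. NF-kB genes were called lower for 5 of 20 (camera adjusted p = 0.018, and adjusted p = 0.0507 with an estimated correlation), against a mean that held IL6Myc-2, and 1 of the 5 was lower than each line singly. In all, 622 genes were higher and 514 lower than the mean of the other lines, and 156 and 161 of them differed from each line singly. Limma on log2(CPM + 1) called 360 higher and 309 lower.

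Several transcripts of the other lines were low or at 0 counts in IL6Myc-1. Cd24a, a surface glycoprotein of B cells, was at 2.86 ± 0.654 CPM against 45.2 to 215 CPM (log2 difference -5.33 ± 0.08, edgeR adjusted p = 3.48e-18). Mfge8, the bridging protein lactadherin, Fat1, an atypical cadherin, and Nckap1, part of the WAVE actin regulatory complex, had 0 counts and were at least 195-fold, 193-fold and 109-fold lower than in the nearest line, although without the reads such a 0 cannot be read as absence of the transcript. Cd200, an inhibitory surface ligand, was at 0.0824 ± 0.0611 CPM against 5.72 to 12.3 CPM, and Tgfb1 at 3.38 ± 0.632 CPM, 3.03-fold below the nearest line. Among signalling genes Socs3, a feedback inhibitor of cytokine signalling, was at 3.78 ± 0.431 CPM and 2.17-fold below the nearest line, and Dusp6, a feedback phosphatase of the MAPK pathway, at 7.92 ± 0.125 CPM and 2.24-fold below it.

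Antigen presentation and B cell genes were also lower in IL6Myc-1. The mature B cell list had 2 of 7 members called lower (camera adjusted p = 1.04e-07), Cd24a and Ebf1, the latter at 6.88 ± 0.692 CPM. MHC class II had 2 of 5 called lower (camera adjusted p = 0.00447), with H2-DMa at 2.204 ± 0.284 CPM, 2.56-fold below the nearest line. The other called gene, Cd74, was at 98.5 ± 2.28 CPM, above the 66.1 CPM of IL6Myc-3, and was lower against a mean that held IL6Myc-2 at 2698 CPM. Class I presentation had 5 of 15 called lower (camera adjusted p = 2.01e-07, lost with an adjusted p = 0.0564 with an estimated correlation), including the immunoproteasome subunit genes Psmb8, at 87.3 ± 4.39 CPM against 205 to 304 CPM, and Psmb9, at 23.6 ± 1.45 CPM, with Tapbp at 60.5 ± 1.98 CPM. The lists of 2 other cell types were not called, with 3 of 8 myeloid markers lower and 1 higher (camera adjusted p = 0.0595) and 2 of 6 T and NK cell markers lower and 1 higher (camera adjusted p = 0.981). The lower myeloid markers were Fcgr4, C1qc and Itgam, and 0 of them was lower than each line singly. A further 4 lists were called and then lost with an estimated correlation. They were, in camera, the immunoglobulin constant list (lower, 1 of 9 called, adjusted p = 0.00488, and adjusted p = 0.196 with an estimated correlation), the IL6 JAK STAT3 list (lower, 3 of 16, adjusted p = 0.0313, and adjusted p = 0.151 with an estimated correlation), the unfolded protein response list (lower in camera, 1 of 26 called higher and 1 lower, adjusted p = 0.0112, and adjusted p = 0.0564 with an estimated correlation) and the proliferation list (higher, 0 of 30, adjusted p = 0.0249, and adjusted p = 0.109 with an estimated correlation).

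Higher in IL6Myc-1 were Abo, the blood group glycosyltransferase gene, at 155 ± 2.39 CPM against at most 0.0159 CPM (1 count), and Baiap2l1, a membrane and actin adaptor gene, at 362 ± 4.25 CPM, 202-fold above the nearest line. Nucb2 was at 37.3 ± 3.19 CPM and 210-fold above the nearest line, and Lncenc1, a non-coding transcript, at 273 ± 8.45 CPM and 6.11-fold above it. Tnfrsf17, the BCMA gene, was at 47.6 ± 3.5 CPM, and its level in the other lines ran from 8.81 ± 0.289 CPM in IL6Myc-2 to 37.1 ± 1.4 CPM in IL6Myc-4. Ccl3, a chemokine that stimulates osteoclasts, was at 3.49 ± 0.112 CPM against at most 0.116 CPM. In all, 517 genes were higher and 955 lower than the mean of the other lines, and 135 and 377 of them differed from each line singly. By limma on log2(CPM + 1), 294 were higher and 630 lower.

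IL6Myc-5 had the highest level of Mcl1, an anti-apoptotic BCL2 family gene on which plasma cells rely, at 1905 ± 54 CPM against 463 to 646 CPM, 2.95-fold above the nearest line (log2 difference 1.75 ± 0.03, edgeR adjusted p = 8.54e-17). Ctss, the lysosomal protease cathepsin S, was at 1416 ± 90.8 CPM and 2.46-fold above the nearest line. Fos, an immediate early gene, was at 182 ± 5.5 CPM against 42.3 to 51.8 CPM, and Dusp5, a MAPK phosphatase, at 152 ± 5.27 CPM and 1.64-fold above the nearest line. The RAS MAPK output list had 4 of 14 members called higher and 0 lower (camera adjusted p = 2.1e-08). Another of these 4, Egr1, was at 0.431 ± 0.0636 CPM, with 2.32 CPM in IL6Myc-3 and 0 counts in IL6Myc-1, and its log2 difference turned to -0.03 with limma on log2(CPM + 1). The mature B cell list was higher (2 of 7 called, camera adjusted p = 1.21e-08), with Cd24a at 215 ± 2.25 CPM. Cd24a was called against a mean that held IL6Myc-1 at 2.86 CPM, and was at 133.1 to 147.5 CPM in the libraries of IL6Myc-3. The glycolysis list was also higher (1 of 20 called, camera adjusted p = 2.33e-08). Its called member was Slc16a3, a lactate exporter gene, at 55.3 ± 9.69 CPM. Slc16a3 was higher in IL6Myc-2, at 63.2 ± 1.3 CPM, and had 0 counts in a whole line. In both lists 0 members were higher than each line singly. Class I presentation was higher with 1 of 15 called (camera adjusted p = 1.67e-07, lost with an adjusted p = 0.0564 with an estimated correlation). MHC class II was called higher by camera (adjusted p = 0.00787), with Ctss called higher and H2-Eb1 lower at 0.419 ± 0.169 CPM, and its median and mean log2 differences of -0.41 and -0.44 were opposite in sign to the test.

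Lower in IL6Myc-5 were the lambda constant genes Iglc2 and Iglc1, at 26.3 ± 1.31 and 38.4 ± 3.73 CPM, 2.99-fold and 2-fold below the nearest line, with 4 of 9 immunoglobulin constant genes called lower (camera adjusted p = 1.09e-16). Of these 4 genes, 2 were lower than each line singly. Igha and Igkc were not among the 4. Their libraries in IL6Myc-5 were at 28780 to 31000 and 22590 to 23320 CPM, above those of IL6Myc-1, IL6Myc-3 and IL6Myc-4. Cd28, a costimulatory receptor of plasma cells, was at 28.4 ± 2.27 CPM against 61.9 to 217 CPM, and the plasma cell identity list had 2 of 19 members called lower, Cd28 and Cd93 (camera adjusted p = 0.00358, with a mean log2 difference of -0.2 and a median of 0.01). NF-kB genes were lower (5 of 20 called, camera adjusted p = 3.45e-05), with Traf1, a TNF receptor adaptor, at 0.837 ± 0.248 CPM and 3.39-fold below the nearest line, and 1 of the 5 was lower than each line singly. Map3k14, at 3.004 ± 0.326 CPM, was called lower against a mean that held IL6Myc-2, and without that line its log2 difference was 0.12. T and NK cell genes were lower (2 of 6 called, camera adjusted p = 0.00307), with Cd3d at 0.0954 ± 0.0368 CPM, as were myeloid genes (1 of 8, adjusted p = 0.029, and adjusted p = 0.147 with an estimated correlation). Lrpap1, a chaperone of lipoprotein receptors, had 3 counts against 17.1 to 27.8 CPM elsewhere, and as a widely expressed gene it cannot be read as absent without the reads. Xlr4a, an X-linked lymphocyte gene with close relatives, was at 0.126 ± 0.0287 CPM against at least 8.93 CPM. In all, 565 genes were higher and 375 lower, and 100 and 71 of them differed from each line singly. On log2(CPM + 1), limma called 276 higher and 215 lower.

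IL6Myc-3 had the smallest numbers of genes set apart from each line singly, 72 higher and 59 lower, out of 542 higher and 359 lower than the mean of the other lines. With limma on log2(CPM + 1), 236 were higher and 190 lower, and in edgeR without the line IL6Myc-1 539 were lower. Scn4a, a voltage-gated sodium channel gene, was at 40.5 ± 7.17 CPM and 34.2-fold above the nearest line (log2 difference 6 ± 0.22, edgeR adjusted p = 1.21e-12). Nid2, a basement membrane protein gene, was 3.18-fold above the nearest line at 15.9 ± 0.592 CPM. Lower were Ptprcap, a partner of the phosphatase CD45, at 4.84 ± 0.421 CPM and 4.74-fold below the nearest line, Sez6l2, at 3.92 ± 0.254 CPM and 4.49-fold below it, and Tnfrsf10b, a death receptor gene and p53 target, at 3.21 ± 0.528 CPM and 2.85-fold below it.

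Several groups were lower in IL6Myc-3. MHC class II had 3 of 5 members called lower (camera adjusted p = 1.26e-09), with Cd74 at 66.1 ± 2.18 CPM and Ctss at 235 ± 8.42 CPM. Cd74 was at 98.5 CPM in IL6Myc-1, and was called against a mean that held IL6Myc-2 at 2698 CPM. Ctss was at 310.3 to 313.3 CPM in the libraries of IL6Myc-4, and its mean held IL6Myc-5, with libraries at 1311 to 1472 CPM. Of the 3 called members, 1 was lower than each line singly. Glycolysis genes were lower as a group (2 of 20 called lower and 2 higher, camera adjusted p = 4.24e-11), with Hk2 at 31.4 ± 0.864 CPM and Aldoc at 26.7 ± 0.777 CPM called lower, and with Pfkm and Slc16a3 called higher, the latter at 6.74 ± 0.237 CPM with a log2 difference that turned to -0.01 with limma on log2(CPM + 1). Slc16a3 was at 63.2 CPM in IL6Myc-2 and 55.3 CPM in IL6Myc-5. Adhesion and homing genes were lower (4 of 19 called lower, 1 higher, camera adjusted p = 0.00223), with Epcam, an epithelial adhesion molecule gene, at 126 ± 1.27 CPM against 234 to 454 CPM. NF-kB genes (2 of 20 called lower, adjusted p = 0.0114), myeloma oncogenes (1 of 19 called higher and 1 lower, adjusted p = 0.00818), BCL2 family genes (0 of 12, adjusted p = 0.00297) and myeloid genes (2 of 8 called lower and 1 higher, adjusted p = 0.000269) were also lower in camera. The called NF-kB genes, Map3k14 and Ltb, were lower against a mean that held IL6Myc-2, and 0 of them was lower than each line singly. In the glycolysis, adhesion, myeloma oncogene and myeloid lists too, 0 members were lower than each line singly. Pim1, counted among the myeloma oncogenes, was at 199 ± 6.65 CPM against 309 to 1135 CPM. The proliferation list was higher with 0 of 30 members called (median log2 difference 0.23, camera adjusted p = 1.15e-05). The IL6 JAK STAT3 list (lower, 2 of 16 called, adjusted p = 0.00153, and adjusted p = 0.0508 with an estimated correlation), the immunoglobulin constant list (lower, 1 of 9, adjusted p = 0.0401, and adjusted p = 0.334 with an estimated correlation) and the therapy target list (lower in camera, 3 of 18 called lower and 1 higher, adjusted p = 0.0372, and adjusted p = 0.136 with an estimated correlation) were lost with an estimated correlation in camera.

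**Figure D3:**
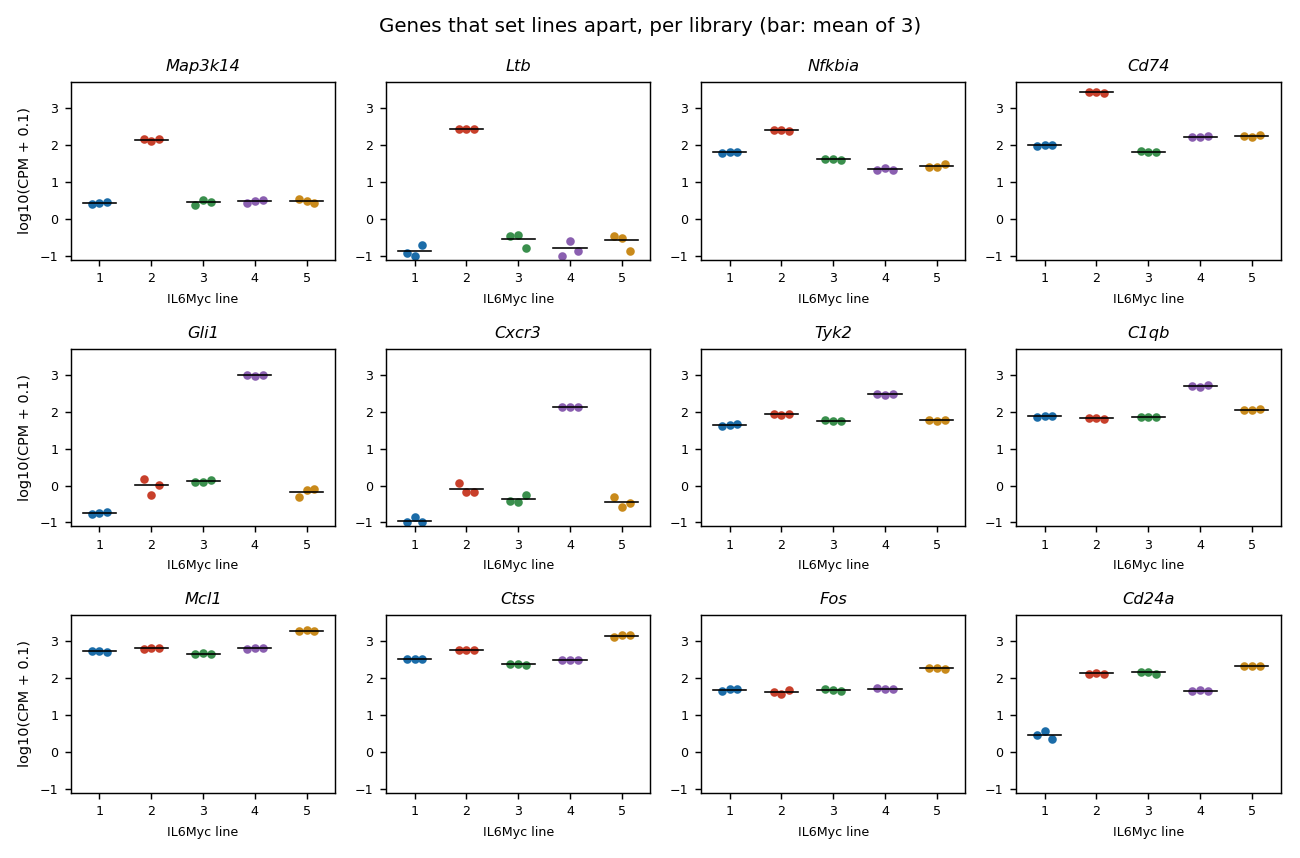
Level of 12 genes that set a line apart, as log10(CPM + 0.1) on the vertical axis, with the lines on the horizontal axis, a point per library and a black bar at the mean of 3. Map3k14, Ltb, Nfkbia and Cd74 stand highest in IL6Myc-2, Gli1, Cxcr3, Tyk2 and C1qb in IL6Myc-4, and Mcl1, Ctss and Fos in IL6Myc-5, and Cd24a stands lowest in IL6Myc-1.

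Some gene groups were called in none of the 5 lines. Of the 32 MYC target and ribosome biogenesis genes, 1 was called in any line, Tfrc, lower in IL6Myc-2, and the smallest camera adjusted p of the list was 0.143. The 20 tested p53 targets had Plk2 called higher in IL6Myc-1, at 21.3 ± 0.305 CPM, and Tnfrsf10b lower in IL6Myc-3 (smallest camera adjusted p = 0.112). The 18 tumour suppressor genes had Cdkn2b, an inhibitor of CDK4 and CDK6, called higher in IL6Myc-1 at 12.1 ± 0.897 CPM and lower in IL6Myc-4 at 3.86 ± 0.414 CPM, and Birc3 higher in IL6Myc-2 at 139 ± 1.38 CPM (smallest camera adjusted p = 0.126). Interferon-stimulated genes (14 tested, smallest camera adjusted p = 0.215), bone disease factors (7 tested, smallest adjusted p = 0.405) and transcripts of the mitochondrial genome (13 tested, smallest adjusted p = 0.151) were not called either. Among their called members were Ifi44, higher in IL6Myc-5 at 8.71 ± 1.43 CPM, Spp1, the osteopontin gene, higher in IL6Myc-4 at 3.47 ± 0.528 CPM, and mt-Nd6, higher in IL6Myc-1 at 95.4 ± 9.91 CPM. Mitochondrial transcripts took 4.67 ± 0.476% to 6.33 ± 0.155% of the counts. In each list and line, the number of called members adjusted over the list alone was the same as that over all genes tested, except for 5 instead of 4 sex-linked genes higher in IL6Myc-2 and 2 instead of 1 interferon-stimulated genes lower in IL6Myc-5. With an estimated correlation, 2 of 7 called lists in IL6Myc-1 and 5 of 9 in IL6Myc-4 stayed called, and each list call printed without such a value kept an adjusted p under 0.05 there. The size of the p-values depended on this setting. For the immunoglobulin constant list in IL6Myc-2 the camera adjusted p rose from 3.05e-42 to 0.000443, and for glycolysis in IL6Myc-3 from 4.24e-11 to 0.00974.

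Sex-linked transcripts separated the lines. The Y-linked genes Eif2s3y and Ddx3y were at 84.4 ± 4.45 and 47.6 ± 0.982 CPM in IL6Myc-2, 47.6 ± 1.41 and 32.8 ± 0.724 CPM in IL6Myc-3, and 42.2 ± 2.59 and 25.6 ± 1.77 CPM in IL6Myc-4. Both had 0 counts in IL6Myc-1 and IL6Myc-5. The sex-linked list was higher in IL6Myc-2 (4 of 8 called, camera adjusted p = 9.84e-08), in IL6Myc-3 (3 of 8, adjusted p = 5.49e-09) and in IL6Myc-4 (3 of 8, adjusted p = 0.00146, and adjusted p = 0.0507 with an estimated correlation). It was not called in IL6Myc-1 (2 of 8 lower, camera adjusted p = 0.571) or IL6Myc-5 (2 of 8 lower, adjusted p = 0.0512). The 2 in IL6Myc-1 were Kdm5d and Uty, and Eif2s3y and Ddx3y were not called there in spite of their 0 counts. Xist, the transcript that silences an X chromosome, was at 0.972 ± 0.34 to 3.24 ± 3.8 CPM.

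The immunoglobulin genes showed the same leading segments in the 5 lines. Igkv4-68 held 99.8% to 99.9% of the counts of the 136 kappa V segments in each line, with 99.779 ± 0.0096% in IL6Myc-3 as the lowest and 99.904 ± 0.0029% in IL6Myc-2 as the highest share. Igkc held 95.1 ± 0.17% to 98.2 ± 0.057% of the light chain constant counts and Igha 97.1 ± 0.057% to 99.1 ± 0.043% of the heavy chain constant counts. Ighg1 and Ighg2a were not among the heavy chain genes counted. The kappa V counts came to 60% to 68.8% of the Igkc counts. In contrast, the counts of all 76 heavy chain V segments came to 0.0233% to 0.109% of the Igha counts, and Ighv11-2 led them in each line with 511 to 1493 counts per line. Among the 3 lambda V segments, Iglv1 led with 78.0 ± 0.61% to 94.6 ± 0.46%. V segments are similar in sequence and change by somatic mutation, so these shares are uncertain where reads fit more than 1 segment.

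Markers of other cell types of the bone marrow were low in the lines. All 19 stromal and endothelial genes, 12 of 13 erythroid and megakaryocyte genes, 17 of 22 myeloid genes and 14 of 18 T and NK cell genes stayed under 5 CPM in every line. The stromal and erythroid lists had 2 and 3 tested members, too few for the list test. The members at 5 CPM or more in at least 1 line were Itga2b, with at most 5.69 CPM, the myeloid genes Cd68, Itgam, Fcgr4, C1qb and C1qc, with at most 202, 11.6, 27.6, 490 and 65.8 CPM, and the lymphocyte genes Cd3d, Cd3g, Cd2 and Prf1, with at most 7.61, 22.0, 81.4 and 14.8 CPM. The neutrophil genes S100a8 and S100a9, the macrophage gene Lyz2 and the globin gene Hba-a1 were at 0.0371 CPM or less in each line. Of the stromal list, the collagen genes Col1a1 and Col1a2 reached at most 0.327 and 0.026 CPM, and Fn1 and Lepr at most 3.62 and 3.05 CPM.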

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

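Among the tests chosen only after the data were seen were edgeR's test, taken once the values were seen to be estimated counts, DESeq2, limma on log2(CPM + 1), other pseudocounts for the distances, and 3 settings for the chromosome shifts. The pseudocount, variance and quantile alternatives, set beforehand for values in TPM, were run in limma on CPM. Leaving out each of the 15 libraries in turn, DESeq2, median-of-ratios scaling, limma on log2(CPM + 0.1), and leaving out immunoglobulin and mitochondrial genes kept the counts of genes and lists that were rerun within 1.5 times, and 0 of the 327 to 342 differences of named genes compared in each of these settings reversed. Blocking on the replicate number did the same, although the numbers do not pair the libraries: 1 of 30 same-numbered pairs of different lines had residuals with r over 0.1. In DESeq2 2 named differences fell short of a threshold they had passed, and in limma on log2(CPM + 1) 54 did. The ratio of distances between and within lines moved by less than 1.5 times on log2(CPM + 0.1) and log2(CPM + 5), and 8 chromosome shifts were called with limma on log2(CPM + 1), with at least 5 CPM in at least 3 libraries, and with immunoglobulin and mitochondrial genes left out. Depth limits the genes at low counts, and 194 of the tested genes had 0 counts in all 3 libraries of at least 1 line, and technical replicates leave the spread between tumours unmeasured.

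Other settings changed the size of the counts. With limma on log2(CPM + 5), 1595 genes differed among the 5 lines, 100, 327, 77, 172 and 104 genes were higher in IL6Myc-1 to IL6Myc-5, and 266, 84, 73, 93 and 66 genes were lower in IL6Myc-1 to IL6Myc-5. Between pairs of lines, by their numbers, the genes differing were 817 for 1 and 2, 342 for 1 and 3, 595 for 1 and 4, 483 for 1 and 5, 520 for 2 and 3, 578 for 2 and 4, 414 for 2 and 5, 345 for 3 and 4, 276 for 3 and 5, 348 for 4 and 5. The cause was not tested.

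In limma on log2(CPM + 1), the counts that moved by over 1.5 times were these: 294 in IL6Myc-1, 236 in IL6Myc-3, 360 in IL6Myc-4 and 276 in IL6Myc-5 were higher, and 630, 248, 190, 309 and 215 genes were lower in IL6Myc-1 to IL6Myc-5. By pair of line numbers, the counts were 832 for 1 and 3, 1217 for 1 and 4, 1138 for 1 and 5, 953 for 2 and 5, 857 for 3 and 4, 668 for 3 and 5, 795 for 4 and 5. Calls shared with edgeR in the same direction numbered 893, 920, 411, 639 and 456 in IL6Myc-1 to IL6Myc-5, of 924, 935, 426, 669 and 491 calls by limma. Without a trend in the limma variance, 294 in IL6Myc-1, 235 in IL6Myc-3, 360 in IL6Myc-4 and 275 in IL6Myc-5 were higher, and 630, 247, 190, 309 and 215 genes were lower in IL6Myc-1 to IL6Myc-5. Between pairs of lines, by their numbers, the genes differing were 831 for 1 and 3, 1216 for 1 and 4, 1138 for 1 and 5, 953 for 2 and 5, 856 for 3 and 4, 667 for 3 and 5, 793 for 4 and 5. After quantile normalization, 621 in IL6Myc-2, 230 in IL6Myc-3, 357 in IL6Myc-4 and 274 in IL6Myc-5 were higher, and 535, 318, 205, 313 and 218 genes were lower in IL6Myc-1 to IL6Myc-5. By pair of line numbers, the counts were 820 for 1 and 3, 1169 for 1 and 4, 1109 for 1 and 5, 864 for 3 and 4, 677 for 3 and 5, 806 for 4 and 5. The cause was not tested.

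Without a filter 21140 genes were tested, and 977, 1758, 1100, 1054 and 983 genes were higher in IL6Myc-1 to IL6Myc-5. With at least 5 CPM in at least 3 libraries 9932 genes were tested, 2449 differed among the lines, 282, 592, 273, 368 and 294 genes were higher in IL6Myc-1 to IL6Myc-5, and 591, 252, 207, 277 and 201 genes were lower in IL6Myc-1 to IL6Myc-5. Between pairs of lines, by their numbers, the genes differing were 1411 for 1 and 2, 787 for 1 and 3, 1137 for 1 and 4, 1042 for 1 and 5, 961 for 2 and 3, 952 for 2 and 4, 808 for 2 and 5, 768 for 3 and 4, 658 for 3 and 5, 744 for 4 and 5. The settings tested more and fewer genes.

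Without a size threshold 10797 genes differed among the lines, 4044, 3933, 3204, 3367 and 3403 genes were higher in IL6Myc-1 to IL6Myc-5, and 3990, 3787, 3105, 3226 and 3053 genes were lower in IL6Myc-1 to IL6Myc-5. By pair of line numbers, the counts were 8347 for 1 and 2, 6832 for 1 and 3, 7759 for 1 and 4, 7713 for 1 and 5, 7359 for 2 and 3, 7071 for 2 and 4, 6638 for 2 and 5, 6258 for 3 and 4, 6511 for 3 and 5, 6274 for 4 and 5. With a log2 difference of at least 2, 1718 genes differed, 164, 431, 236, 223 and 204 genes were higher in IL6Myc-1 to IL6Myc-5, and 463, 162, 100, 227 and 110 genes were lower in IL6Myc-1 to IL6Myc-5. Between pairs of lines, by their numbers, the genes differing were 978 for 1 and 2, 614 for 1 and 3, 811 for 1 and 4, 718 for 1 and 5, 669 for 2 and 3, 734 for 2 and 4, 609 for 2 and 5, 569 for 3 and 4, 421 for 3 and 5, 578 for 4 and 5. These counts follow from the threshold.

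Asked against each of the other 4 lines singly, 135, 364, 72, 156 and 100 genes were higher in IL6Myc-1 to IL6Myc-5, and 377, 130, 59, 161 and 71 genes were lower in IL6Myc-1 to IL6Myc-5, since the stricter definition takes part of the same calls. With an estimated correlation, 2 lists stayed called in IL6Myc-1 and 5 in IL6Myc-4. Without the line IL6Myc-1, 539 genes were lower in IL6Myc-3, and the cause was not tested. With functional segments only, the share of Igkv4-68 in IL6Myc-2 was 99.907%, as fewer segments were counted.

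3 log2 differences of 2 named genes reversed with limma or quantile normalization. Egr1 in IL6Myc-2 went from 1.82 to -0.07 on log2(CPM + 5), -0.15 on log2(CPM + 1) with and without a variance trend, and -0.25 after quantile normalization. Egr1 in IL6Myc-5 went from 2.25 to -0.04, -0.03, -0.03 and -0.04 in the same order, and Slc16a3 in IL6Myc-3 from 3.03 to -0.61, -0.01, -0.01 and 0. These genes had 0 counts in a whole line, so that their fitted log2 difference depends on the prior count. Whether this accounts for the reversals was not tested. Without the line IL6Myc-1, which was low in it, Cd200 in IL6Myc-2 went from 1.69 to 0. Without the line IL6Myc-2, which was high in both, Ighg3 in IL6Myc-4 went from -1.12 to 0.44 and Map3k14 in IL6Myc-5 from -1.29 to 0.12.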

Other observations

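All tests of the immunoglobulin and Y-linked patterns and the scaling test of the chromosome pattern were chosen only after the result was seen. For Xist, the bound under which an inactive X is argued against was raised from 1 to 2 after the ratio of 1.09 had been seen, and under the bound of 1 the outcome was that it cannot be told. The tests on 3 parts of each chromosome were set before their results, and the groupings of libraries were set before the data were examined.

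Genes of several chromosomes moved together, a group that was not among the gene lists. On chromosome 8, 88.6% of 605 genes lay above the mean of the other lines in IL6Myc-5, with a median shift of 0.38 log2 units against all genes. Chromosome 14 was shifted in 3 lines, by 0.36 in IL6Myc-4, with 84.1% of 372 genes on that side, by -0.32 in IL6Myc-1 and by -0.25 in IL6Myc-3. In IL6Myc-5 its shift of 0.19, with 75.3% of genes on that side, fell under the minimum of 0.2. Each line was set against the mean of the other lines, so a rise in a line lowers the others. The shifts of a chromosome are therefore not separate events. In IL6Myc-1, chromosomes 2, 3 and 18 were shifted by 0.33, 0.26 and 0.24, and in IL6Myc-2 chromosome 17, which carries the MHC genes, by 0.29. In all, 8 of 100 tests of a chromosome in a line were called, each with an adjusted p of 0.000425 from 10000 random gene sets, the smallest of the 100, and chromosomes were taken from the GRCm38.p6 assembly. At any size 73 of the 100 had an adjusted p under 0.05, and of the 20 chromosomes of a single simulated comparison 4 had, though 1 was shifted.

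The same kappa segment, Igkv4-68, led in all 5 lines, and reads of other kappa segments assigned to it cannot be told apart from its own, since the low share of any other segment, at most 0.0882% in any library, is also what such assignment would leave. Carry-over of RNA from a single line into the 4 others is argued against by genes abundant in the donor that lay under 10% of the carried level: each donor had at least 37 such genes in 1 of its recipients. That criterion replaced a bound of 10 for every pair of lines after IL6Myc-5 into IL6Myc-3 had given 8. For that pair carry-over would have to bring 1.02 of the donor's level of each gene, and 604 genes were higher in IL6Myc-5 than in IL6Myc-3. A common origin of the lines is a candidate explanation that cannot be told apart from separate use of the segment, because heavy chain V counts came to at most 0.109% of Igha counts and no V-J junction can be read from counts per gene.

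Transcripts of the Y-linked genes Eif2s3y and Ddx3y were at 0 in IL6Myc-1 and IL6Myc-5. Too few reads are argued against by the at least 1798 counts due at the lowest level of the 3 other lines. Of the 15 libraries, 0 had Y counts unlike both others of their line. As both lines were picked for 0 counts in all 3 libraries, that result was fixed for them. A swap between lines alike in Y counts would not show either, so the result does not decide on a mislabelled library. Female cells that kept an inactive X are argued against by Xist, whose highest level in both lines was 0.489 of the highest in the others, and 1.09 of it without IL6Myc-2 replicate 3, while an inactive X would be expected to raise it at least 10 times. Loss of the Y chromosome and female cells without an inactive X may each account for the pattern and cannot be told apart. Uty stood at up to 38.1% of the lowest other line, reads of its X-linked copy may be counted there, and no DNA was analysed here.

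The 8 chromosome-wide shifts of expression were the last pattern. Scaling between the libraries shifts all chromosomes alike. The range of the 20 chromosome medians was at least 0.39 in each line. In 1000 random deals of genes to chromosomes it was at most 0.15. The shifts were already taken against the median of all genes, and each line held a called chromosome. A range above the random one was therefore fixed by the calls, so it restates the pattern and does not decide on scaling. A few neighbouring genes are argued against by 8 of 8 chromosomes with all 3 parts by gene order on the side of the whole, the weakest with medians of 0.03 on chromosome 3 and 0.05 on chromosome 18 in IL6Myc-1. A difference in copy number is a candidate explanation, since 8 of 8 also held in all 3 parts by expression. It cannot be told apart from regulation along a chromosome, as no DNA was analysed here. Each shift is also relative to the other lines, so the shifts do not show in which line a chromosome changed.

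Other groupings of the 15 libraries were run to ask whether chance can be excluded, with 60 groupings for each result on the 5 lines. As the 3 libraries of a line are technical replicates, this sets the lines against technical spread and says nothing about chance between tumours. In that sense chance can be excluded for the 3783 genes differing among the lines, where 1 grouping, the real one, gave as many and the highest other gave 947. It can be excluded for the genes higher and lower in IL6Myc-1 (517 and 955, highest others 8 and 1), in IL6Myc-2 (1013 and 480, highest others 77 and 76) and in IL6Myc-4 (622 and 514, highest others 88 and 73). In IL6Myc-3 2 groupings gave at least 542 higher genes (highest other 615) and 1 gave 359 lower genes (highest other 347). In IL6Myc-5 2 gave at least 565 higher genes (highest other 648) and 1 gave 375 lower genes (highest other 345). Each share was under 0.05, without adjustment over the results. For the higher genes of both lines another grouping exceeded the real one. The groupings were drawn freely, so one could keep the libraries of a line together under another name. Whether that happened was not checked, so the result does not decide on chance there. For gene lists the share was under 0.05 in IL6Myc-2 (10 lists, highest other 9) and IL6Myc-3 (12, highest other 10). The same held for IL6Myc-4 (9, highest other 10) and IL6Myc-5 (10, highest other 10). Other groupings thus called nearly as many lists or more, so these unadjusted shares do not exclude chance for the number of lists. Nor can it be excluded in IL6Myc-1, where 10 groupings gave at least 7 lists and the highest other gave 9.

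For pairs of lines the 10 splits of 6 libraries are too few for a share under 0.05. The real splits gave 1161 to 2238 genes, and the highest other split gave 0, or 1 for IL6Myc-2 with IL6Myc-3 and for IL6Myc-3 with IL6Myc-4.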
